A study of Mus musculus with 31 samples.

How the data were processed

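Poly(A) RNA from mouse livers was sequenced in 31 libraries. The labels give each library a sex and an age but do not state that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical. At 5 months of age there were 6 libraries of wild-type liver (WT), 6 of liver with Myc knocked out (MycKO), 4 with Mlx knocked out (MlxKO) and 5 with both knocked out (DKO), all labelled as fasted for 14 h. A second set held 5 liver adenomas labelled MlxKO, aged 14, 15 or 17 months, and 5 WT livers aged 17 months, all labelled as not fasted. Per the labels, all mice received tamoxifen at 75 mg/kg daily for 5 days, at an age of 28 days, which switches on the Cre recombinase (Cre-ERT2) that deletes the floxed genes. The labels place Cre-ERT2 at the Rosa26 locus in the 5-month knockouts and under an albumin driver in the adenoma mice, and give C57/B6 as the WT strain. Per the labels, WT and MycKO at 5 months held 4 males and 2 females each, MlxKO and DKO held males only, the adenomas came from 4 females and 1 male, and the old WT livers from 2 females and 3 males. The Xist and Y-linked counts of adenoma 5 go against its male label, which the sex term of the main fit kept.

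The authors deposited 1 expression table per age set, holding total counts of reads per gene per library, and the genome build was GRCm38.p6 per the submitters' processing notes. The aligner, the counting tool, the strandedness and the authors' statistical test are not given in the sources used here. Per the labels' protocols, mRNA was enriched with oligo(dT) beads, fragmented and primed with random hexamers, and no molecular identifiers are named, so intervals and floors below cover counting error only. The 5-month table has 41549 genes under Ensembl identifiers, of which 41474 matched by identifier to the reference table of gene names and 20937 had no count in any library. The old-liver table has 36333 genes under Entrez identifiers, of which 35337 matched by identifier to the RefSeq gene table of the same build and 14200 had no count. The authors' deposited tables also hold log2 fold changes and p-values for their own comparisons, in which an adjusted p is listed as 0 at genes with few or no counts. The sources used here do not say why, and such genes were left out of the counts of the authors' calls. The 63 and 30 normalized columns of the 2 tables were not used, and no count column was without a sample.

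Total counts per library ran from 18226467 to 28476797 at 5 months, from 16036626 to 18690029 in the old WT livers and from 34590164 to 37087490 in the adenomas. In the adenoma libraries 81.0 to 83.1% of the counts between 1 and 19 were even numbers, against 42.3 to 44.1% in the old WT livers of the same table. Counting both reads of each pair gives mostly even counts, and whether this was done is not given in the sources used here, so halved adenoma counts were tried as an alternative. Across replicates the common biological coefficient of variation was 0.261 at 5 months (16 residual degrees of freedom) and 0.385 in the old livers (7 residual degrees of freedom). No 2 replicates agreed within sampling noise, and the closest, MlxKO 3 and 4, still had a chi-square of 16.1 per gene.

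Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10) on the groups, library sizes were scaled by TMM, and group means plus a term for sex were fitted by the quasi-likelihood method (glmQLFit, glmQLFTest). Each age set was fitted on its own with all of its libraries, so that groups share an estimate of the spread, and no test crosses the 2 sets. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, 13397 at 5 months and 13954 in the old livers, and all adjusted p-values of genes are from this test. Fold changes are log2 with their standard error (SE). They come from the fit with its sex term, so a fold can differ from the ratio of the group means printed beside it. Levels are CPM (counts scaled to a common library total) with TMM-scaled library sizes, as mean ± SD, unless plain CPM is stated. The 7 tests were MycKO, MlxKO and DKO against WT, DKO against MycKO, DKO against MlxKO, the departure from additive effects on the log scale (Myc by Mlx interaction), and adenoma against old WT.

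The gene lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. There were 50 lists, 39 of pathways and gene classes and 11 of cell type markers. Each was tested against the other genes with limma's camera (limma 3.58.1) at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, with at least 5 measured members needed. Marker lists of adipocytes and pancreatic acinar cells had too few measured members in all comparisons, and mitochondrially encoded genes in the adenoma comparison. Camera with an estimated correlation kept only the list of ChREBP targets and fructolysis (MlxKO and DKO against WT, DKO against MycKO) and nucleotide and one-carbon synthesis (DKO against MlxKO). Fry, which asks whether a list's genes move one way on balance and does not compare the list with other genes, was also run. The genes named are Myc, Mlx and the changed members of their network. For up to 8 lists with the smallest camera p come up to 4 changed members in the direction of the list. Last come the 6 largest rises and 6 largest falls among changed genes with at least 1 CPM in a group and every library of the first group on the same side of the mean of the other, predicted genes and pseudogenes skipped. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here.

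The alternatives were DESeq2 1.42.0, RLE factors, no filter or a filter at 1 CPM, no sex term, limma-voom, a fold minimum, removal of genes within 10 Mb of Myc, Mlx or the Rosa26 locus, libraries of 1 sex, a fit with only the groups compared, the 17-month adenomas alone, and each library left out. Alternatives chosen after the data were seen were the removal of WT 2, WT 5 and MycKO 5, offsets for gene length and GC content (splines with 5 degrees of freedom), halved adenoma counts, adenoma 5 taken as female, and a term shared by the WT females, MlxKO and DKO. Fold bounds against a group at 0 use a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval. For each test, 100 splits of the libraries into groups of the same sizes, the real one included, were refitted. Pairs of 5-month comparisons were set against 20 simulated tables with no effect, and those that share WT libraries also against 10 divisions of the WT libraries, each used both ways round. The pair of MlxKO against WT and DKO against MycKO was also fitted with the shared term, in the data and in 20 simulated tables.

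The fits were tested on simulated data with 200 genes changed by known factors. At a 2-fold change the share recovered was 65.7% for MycKO against WT, 56.7% for MlxKO against WT, 50.7% for DKO against WT, 55.2% for DKO against MycKO, 47.8% for DKO against MlxKO, 25.4% for the interaction and 11.9% for adenoma against WT. At 4-fold these shares were 90.9, 81.8, 92.4, 87.9, 86.4, 75.8 and 71.2%, and at 1.5-fold they were 16.4, 17.9, 29.9, 20.9, 17.9, 1.49 and 0%, in the same order. False calls made up 3.36, 7.14, 1.71, 0.909, 1.94, 2.86 and 3.51% of the calls. Neither these simulated data nor the simulated tables with no effect held differences by sex or other structure shared by genes across libraries. The shares recovered and the shares of false calls therefore need not hold in the real libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.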

Results

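RNA from mouse liver was sequenced to ask how transcription changed when Myc, Mlx or both were deleted, and how adenomas that arose in Mlx-deleted livers differed from old liver. Myc is a transcription factor of growing cells. Mlx is the shared partner of MondoA (Mlxip) and ChREBP (Mlxipl), transcription factors that respond to glucose. The 5-month set held 6 WT, 6 MycKO, 4 MlxKO and 5 DKO libraries, and the old set held 5 adenomas labelled MlxKO and 5 WT livers of 17 months. Total counts ran from 18226467 to 28476797 at 5 months, from 16036626 to 18690029 in old WT and from 34590164 to 37087490 in the adenomas, whose low counts were mostly even numbers. On the first principal component the old set parted into adenomas and WT, with 43.9% of the variance. At 5 months the first component held 23.1% and the second 17.8%, and WT 2, WT 5 and MycKO 5 lay apart from the other libraries on the second. On the third, with 11%, WT 1, MycKO 1 and MycKO 2 lay apart (−45.1, −44.2 and −44, next −13.5), and they were not left out together. Adenoma 5, the library labelled male, had 984.83 plain CPM of Xist and 0 counts over 4 Y-linked genes, while the 4 adenomas labelled female had 665.83 to 810.86 plain CPM of Xist. Reads from the mitochondrial genome made up 5.36% ± 0.544 (SD, n = 6) of counts in WT, 5.03% ± 0.472 (n = 6) in MycKO, 6.51% ± 0.839 (n = 4) in MlxKO and 6.85% ± 1.60 (n = 5) in DKO. They made up 0.126% ± 0.044 (n = 5) in the adenomas and 0.124% ± 0.087 (n = 5) in old WT. The list of mitochondrially encoded genes had too few measured members to be tested in the old set, unlike at 5 months. The shares of the 2 sets thus may not cover the same genes and are not compared.

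The targeted genes were read in every library first. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374, plus strand, GRCm38) stood at 12.9 CPM ± 6.75 (n = 6) in WT, 1.67 ± 0.692 (n = 6) in MycKO, 10.0 ± 3.18 (n = 4) in MlxKO and 1.31 ± 0.728 (n = 5) in DKO. No MycKO or DKO library exceeded 2.61 CPM, and no WT or MlxKO library was under 3.61 CPM. Mlx (ENSMUSG00000017801, chromosome 11, 101087277 to 101092207, plus strand) stood at 26.4 CPM ± 1.95 (n = 6) in WT, 24.4 ± 2.27 (n = 6) in MycKO, 19 ± 2.28 (n = 4) in MlxKO and 17.0 ± 1.45 (n = 5) in DKO. With TMM-scaled sizes every MlxKO and DKO library was below every WT and MycKO library. In the old set Mlx was 25.3 CPM ± 4.14 (n = 5) in adenomas and 38.7 ± 5.38 (n = 5) in WT, and Myc was 12.7 ± 5.49 and 4.43 ± 3.53. The labels do not say which exons are floxed, and the deposited counts cover each gene as a whole, so a transcript that lacks only the deleted part would still be counted.

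**Figure D1:**
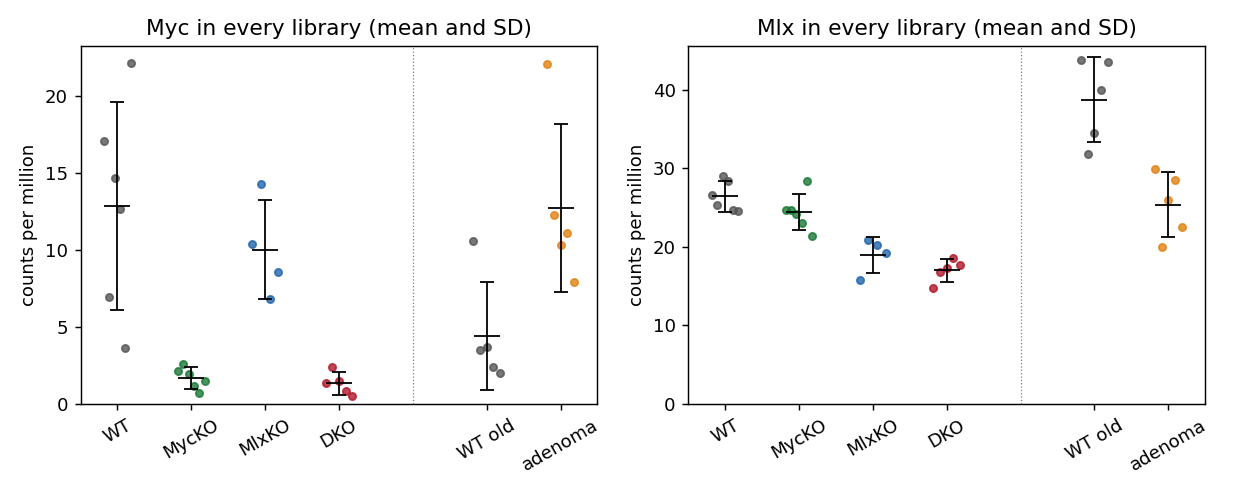
CPM of Myc (left) and Mlx (right) in each library of the 6 groups, with horizontal bars at the mean and the SD. MycKO and DKO libraries lie at or below 2.61 for Myc, and MlxKO and DKO libraries lie between 14.7 and 20.8 for Mlx, below all 5-month WT libraries.

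Few single genes changed in MycKO against WT at 5 months. The labels place Cre-ERT2 at Rosa26 in the 5-month knockouts and give C57/B6 as the WT strain. In every 5-month comparison that uses WT, gene loss therefore cannot be told apart from effects of Cre-ERT2 or strain. Myc itself fell 7.69-fold (log2 fold change −2.94 ± 0.41 SE, adjusted p = 0.0033). The largest rise was that of Cd8a, a co-receptor of cytotoxic T cells, from 0.0768 CPM ± 0.0558 in WT to 1.12 ± 0.479 in MycKO (13.9-fold, adjusted p = 0.0011). Pvt1, a noncoding RNA gene next to Myc, rose 4.27-fold, the dynein light chain Dynlt1b 2.03-fold and the immunoproteasome subunit Psmb9 1.91-fold, at adjusted p = 0.029, 0.037 and 0.029. Among the falls were Rpl12, a protein of the large ribosomal subunit (log2 −0.74 ± 0.13), Gpatch4 (−0.75 ± 0.14), the pro-apoptotic Bid (−1.07 ± 0.17), and Mug2, a secreted protease inhibitor (−3.10 ± 0.56), at adjusted p of 0.029, 0.038, 0.015 and 0.029. Bid and Mug2 were also low in MlxKO, where Myc was not deleted. Bid stood there at 5.92 CPM ± 0.714 against 11.5 ± 1.75 in WT, and Mug2 at 20.3 ± 7.17 against 319 ± 94.3. Their falls are thus not particular to loss of Myc. Gt(ROSA)26Sor, the noncoding RNA of the Rosa26 locus in which the labels place Cre-ERT2, fell by 1.67 ± 0.27 on the log2 scale (adjusted p = 0.015). BC018473 had 2 counts over the MycKO libraries and 220 over WT, a ratio of 128 after scaling (95% counting interval 35.1 to 1060), but WT itself was split, from 0 to 7.69 CPM. Mlx did not pass the test (−0.11 ± 0.09, adjusted p = 0.84, lower in 5 of 6). Each gene named as changed in this and later comparisons had all libraries of its first group on the same side of the mean of the second, except where stated.

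Genes of protein synthesis lay lower as groups in MycKO by camera at its preset correlation, but none of these lists passed with an estimated correlation. Of 79 cytoplasmic ribosomal protein genes, 1 passed the test over all genes (DESeq2 called 14) and 38 were lower when adjusted over the list alone, with a median log2 fold change of −0.33. As a list they moved down against other genes (camera adjusted p = 3.55e-40, adjusted p = 0.282 with an estimated correlation). The median was −0.21 in males only and with a term shared by the WT females, MlxKO and DKO, and Rpl12, the gene called, did not pass in either (adjusted p = 0.35 and 0.31). In edgeR 0 of the list also passed without genes near the targeted loci, in a fit of these groups alone and without WT 2, WT 5 and MycKO 5. So it was without each of WT 2, WT 3, WT 4, MycKO 1, MycKO 3, MycKO 4 and MycKO 6, while other settings called 1 to 4. With that shared term edgeR, DESeq2 and limma-voom called 0 of the list, and 18 were lower at an unadjusted p under 0.05. Of 63 ribosome biogenesis genes, 0 passed in edgeR over all genes, 26 were lower at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Adjusted over the list alone 13 were lower (median −0.23, camera adjusted p = 4.56e-19, adjusted p = 0.0941 with an estimated correlation). Translation factors and tRNA synthetases, 57 genes, had a median of −0.14 (camera adjusted p = 1.02e-09, adjusted p = 0.282 with an estimated correlation). Urea cycle and amino acid catabolism had a median of −0.23 (camera adjusted p = 1.22e-07, adjusted p = 0.328 with an estimated correlation). Markers of T and NK cells went the other way, with 1 of 14 risen over all genes, 5 adjusted over the list alone and a camera adjusted p of 2.49e-10 (adjusted p = 0.0941 with an estimated correlation). Camera also placed interferon response genes (median 0.20, adjusted p = 0.000879, and adjusted p = 0.844 with an estimated correlation) and neutrophil markers (median 0.88, adjusted p = 0.00898, and adjusted p = 0.614 with an estimated correlation) higher than other genes.

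In all, 12 of 13397 genes changed in MycKO against WT, 4 up and 8 down, and 1027 had an unadjusted p under 0.05 where 670 are due to chance. The 12th, Gm10184, (chromosome 17, 89908462 to 89910449) is a near-identical copy of Kpna2 (chromosome 11, 106988629 to 106999541), so its value is uncertain, and BC018473 lies on chromosome 11, 116752167 to 116759373. Of 10 changed genes other than Myc and Gt(ROSA)26Sor, 3 (Bid, Mug2 and Pvt1) lay within 10 Mb of Myc, Mlx or Rosa26, where 0.298 were due to chance (one-sided Fisher's exact test, p = 0.0027), and with genes in these windows left out 1 gene passed. The count was 2 in males only, 1 in a fit of these groups alone (Myc adjusted p = 0.071), 7 with no sex term and 71 with DESeq2. Leaving out 1 library gave 4, 2, 7, 2, 7 and 25 genes without WT 3, WT 4, MycKO 1, MycKO 3, MycKO 4 and MycKO 5. The authors' deposited table lists 25 genes.

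**Figure D2:**
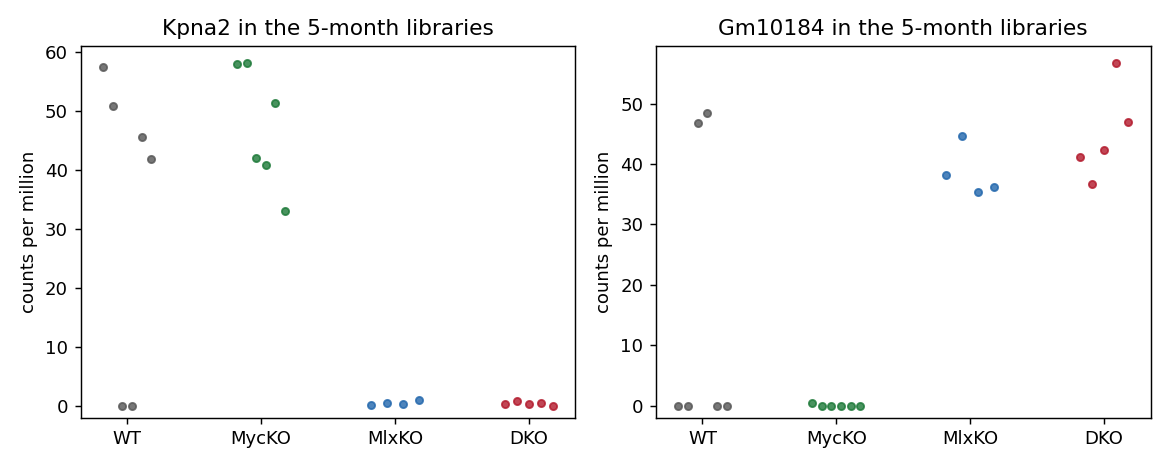
CPM of Kpna2 (left) and its near-identical copy Gm10184 (right) in each 5-month library. Libraries with Kpna2 between 33.1 and 58.1 have Gm10184 at or below 0.434, and libraries with Kpna2 at or below 1.01 have Gm10184 between 35.3 and 56.7.

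Among the genes that fell with loss of Mlx were ChREBP targets and genes of fructolysis. Tkfc, the triose kinase of fructose breakdown, fell 3.23-fold in the fit with its sex term (log2 −1.69 ± 0.23, adjusted p = 0.0017). Its means over both sexes were 404 CPM ± 270 in WT and 82.2 ± 7.68 in MlxKO. Pklr, liver pyruvate kinase, fell 4.82-fold, from 62.5 CPM ± 23.0 to 11.5 ± 1.86 (adjusted p = 0.0067). Me1, malic enzyme, fell 2.0-fold (adjusted p = 0.0067), and Slc2a2, the glucose transporter GLUT2, fell 9.37-fold, from 125 CPM ± 73.6 to 12.8 ± 9.45 (adjusted p = 0.018). The repressor Bcl6 rose 6.38-fold, from 5.53 CPM ± 2.93 to 34.0 ± 13.9 (adjusted p = 0.0067).

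Of 29 measured ChREBP targets and genes of fructolysis, 6 fell in MlxKO over all genes, while 12 were lower and 1 higher adjusted over the list alone (median −0.42). This list passed camera (adjusted p = 9.38e-08) and also the estimated correlation (adjusted p = 0.00525). Of 79 cytoplasmic ribosomal protein genes only Rps15a passed over all genes (log2 −0.59 ± 0.14, adjusted p = 0.029), and 68 were lower adjusted over the list alone (median −0.47, camera adjusted p = 2.4e-23, adjusted p = 0.483 with an estimated correlation). Of these ribosomal genes DESeq2 called 36 and limma-voom 1, while edgeR called 52 without WT 6 and 12 with the shared term, and 0 to 4 under its other settings. The median was −0.79 with the shared term and −0.22 with length and GC offsets. Of 35 interferon response genes 2 fell, Irf7 (−1.30 ± 0.30) and Bst2 (−1.02 ± 0.25), and 13 were lower adjusted over the list alone (median −0.92, camera adjusted p = 3.8e-09, adjusted p = 0.483 with an estimated correlation). Markers of Kupffer cells, the resident macrophages of liver, had a median of −0.62, with 3 of 18 lower adjusted over the list alone (camera adjusted p = 4.21e-05, adjusted p = 0.489 with an estimated correlation). Secreted liver proteins had 4 falls of 37, in Kng1 (−0.70 ± 0.15), Vtn (−0.67 ± 0.15), the coagulation factor F10 (−0.74 ± 0.17) and Ambp (−0.69 ± 0.16), with a camera adjusted p of 1.46e-07 (adjusted p = 0.238 with an estimated correlation). Male-biased genes had 2 falls of 29, Mup20 (−1.22 ± 0.27) and Cspg5 (−2.95 ± 0.76, adjusted p = 0.050). Their median was −0.95, and without the sex term, which sets the male MlxKO libraries against WT of both sexes, it was −0.35 with the test's direction turned. Among males alone every MlxKO library was below every WT library for Mup20 (3540 to 4420 against 6830 to 10900 CPM). The same held for Cspg5 (0.238 to 1.16 against 1.3 to 7.58 CPM). DESeq2 called falls in 10 of the ChREBP targets, 11 of the interferon response genes, 10 of the secreted liver proteins and 7 of the male-biased genes.

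Lists of mitochondrial genes lay lower in MlxKO by camera, but each of 3 had adjusted p = 0.604 with an estimated correlation, and 0 members passed edgeR over all genes. At an unadjusted p under 0.05 36 mitochondrial ribosomal proteins, 17 genes of complex I and 20 of complexes II to V were lower, DESeq2 called 4, 2 and 1 of them, and limma-voom called 0. The medians were −0.33 for 78 mitochondrial ribosomal proteins (camera adjusted p = 3.8e-09, adjusted p = 0.604 with an estimated correlation) and −0.44 for 36 genes of OXPHOS complex I (camera adjusted p = 7.82e-08, adjusted p = 0.604 with an estimated correlation). For 39 genes of complexes II to V the median was −0.39 (camera adjusted p = 2.15e-07, adjusted p = 0.604 with an estimated correlation). Of 42 fatty acid oxidation and PPAR alpha targets 5 rose over all genes (8 with DESeq2) and 10 were higher adjusted over the list alone (median 0.24, camera adjusted p = 3.44e-06, adjusted p = 0.483 with an estimated correlation). Of 28 ER stress genes 2 rose, with 11 higher and 2 lower adjusted over the list alone (median 0.58, camera adjusted p = 0.000599, adjusted p = 0.604 with an estimated correlation). In this list limma-voom called 0, DESeq2 called 9 up and 2 down, and 13 were higher and 2 lower at an unadjusted p under 0.05 in edgeR. With the shared term camera's direction turned for both lists, with medians of −0.06 for fatty acid oxidation and 0.19, still positive, for ER stress. The largest changes beyond these lists were rises of the homeobox gene Pknox2 (log2 2.79 ± 0.38), the lipoprotein receptor Vldlr (2.42 ± 0.36), the histone gene H1f3 (2.45 ± 0.62) and Cpne5 (4.0 ± 1.0). The falls were those of Serpina12, a serpin (−6.21 ± 1.47), Mug2 (−4.65 ± 0.71), Zfp708 (−3.69 ± 0.80) and Sstr2, a somatostatin receptor (−3.20 ± 0.59). BC018473 and Kpna2 also passed but are uncertain, because WT libraries fell into separate levels for both.

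In all, 227 of 13397 genes changed in MlxKO against WT, 85 up and 142 down, and Mlx itself fell 1.37-fold (log2 −0.46 ± 0.11, adjusted p = 0.039) while Myc did not pass the test (−0.36 ± 0.44, adjusted p = 0.65, lower in 3 of 4). The count was 96 in males only, 38 in a fit of these groups alone, 82 without WT 2, WT 5 and MycKO 5, 122 with no sex term and 846 with DESeq2, and 664 with the shared term, 381 up and 283 down, of which 93 were among the 227. Mlx lost its call in males only (adjusted p = 0.1), in the fit of these groups alone (0.21), without WT 2, WT 5 and MycKO 5 (0.082), with no filter (0.082) and with length and GC offsets (0.17). It also lost it without WT 1 (0.054), WT 2 (0.074), WT 3 (0.053), WT 5 (0.054), MlxKO 1 (0.11), MlxKO 2 (0.065), MlxKO 3 (0.079) and MlxKO 4 (0.11). Without single libraries the count was 92 (WT 2), 137 (WT 5), 1055 (WT 6), 75 (MlxKO 2), 69 (MlxKO 3) and 45 (MlxKO 4). The authors' deposited table lists 253.

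With both genes deleted, ribosomal protein genes were lower almost throughout. In DKO 77 of 79 cytoplasmic ribosomal protein genes fell, with a median log2 fold change of −0.96. Rps10 fell from 176 CPM ± 34.5 to 69.6 ± 12.9 (log2 −1.29 ± 0.15) and Rpl12 from 160 ± 34.3 to 64.5 ± 5.18 (−1.27 ± 0.15), both at adjusted p = 6.5e-05. At the same adjusted p Rpl36a fell from 80.7 ± 14.6 to 33.6 ± 5.62 (−1.24 ± 0.14) and Rpl15 from 198 ± 36.1 to 84.4 ± 8.90 (−1.18 ± 0.14). All 79 were lower adjusted over the list alone (camera adjusted p = 1.04e-75, adjusted p = 0.117 with an estimated correlation). Ribosome biogenesis genes had 19 falls of 63, among them nucleophosmin Npm1 (−0.70 ± 0.12), Nop16 (−0.74 ± 0.16), Polr1c (−0.73 ± 0.15) and Nop2 (−0.62 ± 0.13). Of the 63, 27 were lower adjusted over the list alone (camera adjusted p = 7.74e-06, adjusted p = 0.354 with an estimated correlation).

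Many genes of mitochondrial ribosomes and of the respiratory chain fell in DKO. Of 78 mitochondrial ribosomal proteins 45 fell, such as Mrpl20 (log2 −0.88 ± 0.13), Mrpl11 (−0.87 ± 0.18), Mrpl40 (−0.59 ± 0.13) and Mrpl38 (−1.03 ± 0.22). Of the 78, 56 were lower adjusted over the list alone (camera adjusted p = 1.63e-15, adjusted p = 0.354 with an estimated correlation). Of 36 complex I genes 20 fell, including Ndufa1 (−1.26 ± 0.24), Ndufb4 (−0.88 ± 0.17), Ndufa6 (−0.68 ± 0.14) and Ndufa13 (−0.92 ± 0.22). Of the 36, 29 were lower adjusted over the list alone (camera adjusted p = 4.74e-10, adjusted p = 0.38 with an estimated correlation). Of 39 genes of complexes II to V 20 fell, including Atp5g2 (−0.69 ± 0.13), Cox8a (−0.88 ± 0.17), Uqcr11 (−1.41 ± 0.32) and Cox5b (−1.19 ± 0.28). Of the 39, 26 were lower adjusted over the list alone (camera adjusted p = 4.51e-09, adjusted p = 0.413 with an estimated correlation). The 13 measured genes of the mitochondrial genome had a median of 0.17 (camera adjusted p = 0.245), and 0 passed in edgeR, DESeq2 or limma-voom, with 1 higher at an unadjusted p under 0.05.

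Some genes of fatty acid oxidation and of the unfolded protein response rose in DKO. Of 42 fatty acid oxidation and PPAR alpha targets 16 rose, including the thioesterase Acot2 (log2 2.57 ± 0.36), Pex11a (1.39 ± 0.24) and Aldh3a2 (1.16 ± 0.20). Adjusted over the list alone 22 were higher (camera adjusted p = 1.31e-09, adjusted p = 0.247 with an estimated correlation). Of 28 ER stress genes 14 rose and 1 fell, with the chaperone Hspa5 (BiP) up from 427 CPM ± 210 to 1940 ± 791 (log2 2.39 ± 0.43), Dnajb9 up by 1.06 ± 0.20 and Sel1l by 1.15 ± 0.23 on the log2 scale. Adjusted over the list alone 18 were higher and 2 lower (camera adjusted p = 1.2e-06, adjusted p = 0.354 with an estimated correlation). Derl3, of ER-associated degradation and also on the list of plasma cell markers, rose from 0.577 CPM ± 0.634 to 48.6 ± 42.3, with DKO libraries between 4.43 and 98.1. Of 29 ChREBP targets 11 fell over all genes, and 12 were lower adjusted over the list alone, among them Tkfc (−2.05 ± 0.22, adjusted p = 4.6e-05), Pklr (−2.52 ± 0.36), Me1 (−1.09 ± 0.16) and ketohexokinase Khk (−1.94 ± 0.34). That list passed camera (adjusted p = 2.42e-06) and the estimated correlation (adjusted p = 0.0204).

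Markers of other cell types moved with these groups in DKO. Of 18 markers of Kupffer cells and macrophages 9 fell (median −0.88, 10 lower adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.354 with an estimated correlation). Of 6 erythroid markers 5 fell (median −1.48, camera adjusted p = 0.0174, adjusted p = 0.38 with an estimated correlation), as many at an unadjusted p under 0.05 and with DESeq2, while limma-voom called 0. Of 11 cholangiocyte markers 2 rose (median 0.70, camera adjusted p = 0.00442, adjusted p = 0.354 with an estimated correlation). Of 35 interferon response genes 5 fell, or 11 with DESeq2 (median −0.60, camera adjusted p = 0.000204, adjusted p = 0.468 with an estimated correlation). Secreted liver proteins had 15 falls and 1 rise of 37 (median −0.47, camera adjusted p = 9.22e-06, adjusted p = 0.263 with an estimated correlation). Alb, chosen after its values were seen, did not pass the test (−0.15 ± 0.20, adjusted p = 0.64, lower in 4 of 5). Further large changes were rises of Cpne5 (log2 4.55 ± 0.99), the thioesterase Acot5 (4.23 ± 0.97), the lysophosphatidic acid receptor Lpar3 (3.65 ± 0.58) and the water and glycerol channel Aqp3 (3.44 ± 0.70). Falls were those of Serpina12 (−5.16 ± 1.21), the ion channel Hcn3 (−5.09 ± 0.60), the steroid enzyme Hsd3b5 (−4.95 ± 1.27), Mug2 (−4.57 ± 0.65) and Obp2a (−4.08 ± 0.74), with BC018473 and Kpna2 uncertain as above.

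In all, 2475 of 13397 genes changed in DKO against WT, 1015 up and 1460 down, of which 595 by at least 2-fold. Myc fell 9.76-fold (log2 −3.29 ± 0.46, adjusted p = 0.00018) and Mlx fell 1.53-fold (−0.61 ± 0.10, adjusted p = 0.00089). The Myc relative Mycl fell 2.84-fold in the fit with its sex term (adjusted p = 0.0053), with means of 19.8 CPM ± 12.4 in WT and 4.57 ± 1.22 in DKO. The count was 1520 in males only, 1220 in a fit of these groups alone, 1298 without WT 2, WT 5 and MycKO 5, 1514 with length and GC offsets and 1520 with the shared term, 753 up and 767 down, of which 943 were among the 2475. It was 1218, 1468 and 1597 without WT 2, DKO 4 and DKO 5. The authors' deposited table lists 1891.

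**Figure D3:**
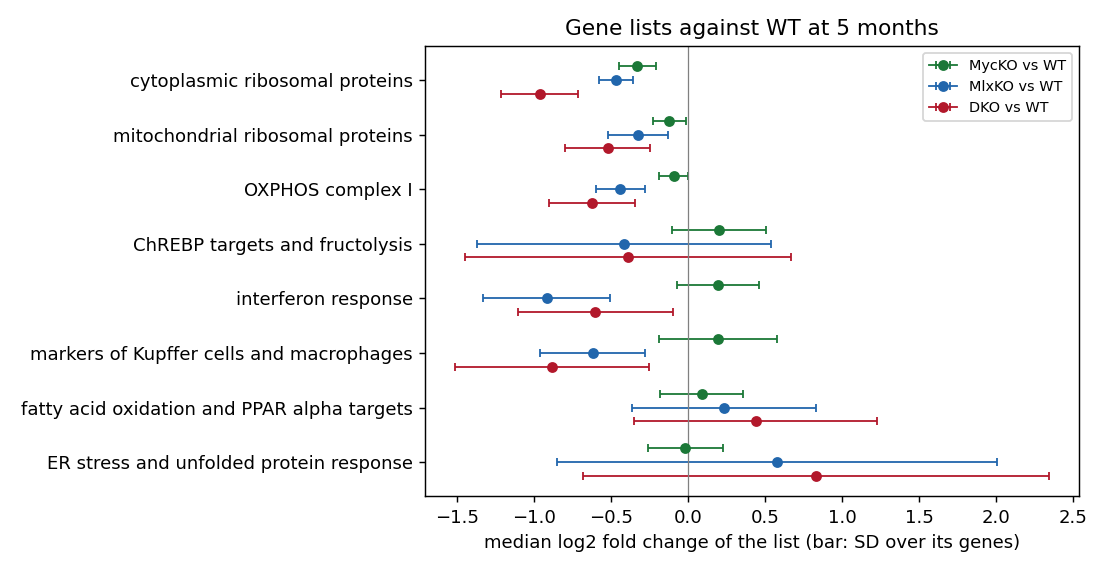
Median log2 fold change against WT at 5 months for 8 gene lists, in MycKO, MlxKO and DKO, with bars for the SD over the genes of a list. Cytoplasmic ribosomal proteins stand at −0.33, −0.47 and −0.96 in the 3 knockouts, and interferon response genes at 0.20 in MycKO and −0.92 in MlxKO.

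DKO against MycKO asks what loss of Mlx adds where Myc is already absent. ChREBP targets and genes of fructolysis were again lower, with Tkfc down 4.82-fold (log2 −2.27 ± 0.22, adjusted p = 4.8e-06), Pklr down 8.91-fold, from 101 CPM ± 56.4 to 9.70 ± 2.53, Me1 down 2.29-fold and the fatty acid elongase Elovl6 down 3.81-fold. Of 29 ChREBP targets 14 fell over all genes, and 15 were lower and 1 higher adjusted over the list alone (camera adjusted p = 6.52e-10, and adjusted p = 0.00132 with an estimated correlation). Of 79 ribosomal protein genes 66 fell, such as Rpl35a (−1.34 ± 0.19), Rpl13a (−1.10 ± 0.17), Rps10 (−0.92 ± 0.15) and Rpl15 (−0.85 ± 0.14). Adjusted over the list alone 73 were lower (median −0.62, camera adjusted p = 1.19e-38, adjusted p = 0.315 with an estimated correlation). With length and GC offsets 40 fell (median −0.43). With the shared term (median −1.11) edgeR called 0, while 69 were lower at an unadjusted p under 0.05, DESeq2 called 42 and limma-voom 2.

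Of 35 interferon response genes 13 fell in DKO against MycKO, including Bst2 (log2 −1.39 ± 0.23), Ifi27l2a (−2.09 ± 0.40), Irf7 (−1.37 ± 0.27) and Rtp4 (−1.24 ± 0.25). Of the 35, 19 were lower adjusted over the list alone (camera adjusted p = 1.5e-09, adjusted p = 0.331 with an estimated correlation). Of 18 Kupffer cell and macrophage markers 10 fell, including Cd5l (−1.55 ± 0.25) and the complement genes C1qa (−1.49 ± 0.24), C1qc (−1.38 ± 0.23) and C1qb (−1.22 ± 0.23). Of the 18, 13 were lower adjusted over the list alone (camera adjusted p = 1.5e-09, adjusted p = 0.291 with an estimated correlation). Of 14 T and NK cell markers 3 fell, or 5 with limma-voom (median −1.12, camera adjusted p = 0.00039, adjusted p = 0.331 with an estimated correlation). ER stress genes had 14 rises of 28, including Hspa5 (2.28 ± 0.40), Derl3 (6.12 ± 1.10), Dnajb9 (1.08 ± 0.20) and the transcription factor Ddit3 (CHOP, 1.59 ± 0.29), with a camera adjusted p of 1.5e-09 (adjusted p = 0.331 with an estimated correlation). Fatty acid oxidation genes had 12 rises of 42 (19 with DESeq2), including Cpt2 (0.67 ± 0.13), Acot2 (1.79 ± 0.36) and Acot3 (1.57 ± 0.37, higher in 4 of 5), with a camera adjusted p of 7.32e-08 (adjusted p = 0.331 with an estimated correlation). With the shared term their median was −0.10.

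Mitochondrial ribosomal proteins had 23 falls of 78 in DKO against MycKO, including Mrpl20 (log2 −0.81 ± 0.13), Mrpl40 (−0.57 ± 0.12), Mrpl14 (−1.11 ± 0.25) and Mrpl11 (−0.75 ± 0.17). Complex I had 13 falls of 36, including Ndufa1 (−1.42 ± 0.24), Ndufa6 (−0.62 ± 0.14), Ndufa8 (−0.95 ± 0.22) and Ndufa13 (−0.91 ± 0.21). Both lists passed camera (adjusted p = 7.93e-10 and 6.52e-09) and neither passed the estimated correlation (adjusted p = 0.548 for each). The 13 genes of the mitochondrial genome had a median of 0.34 and a camera adjusted p of 0.0457 (adjusted p = 0.734 with an estimated correlation). Of these 0 passed in edgeR or limma-voom and 2 in DESeq2, 3 were higher at an unadjusted p under 0.05, and with the shared term the median was −0.15. Single genes with large rises were the chemokine-like Msmp (3.53 ± 0.69), Lpar3 (3.11 ± 0.56), the kinase Pak6 (2.75 ± 0.42) and Aqp3 (2.73 ± 0.71). Large falls were seen for Hsd3b5 (−6.28 ± 1.31), Serpina12 (−5.96 ± 1.15), Hcn3 (−5.38 ± 0.61) and Obp2a (−5.02 ± 0.74). The MycKO means of Hsd3b5 and Serpina12 rest largely on MycKO 5. It had 181 CPM of Hsd3b5 against 6.12 at most in the other MycKO libraries, and 38.6 of Serpina12 against 8.35 at most. Ptgds, a prostaglandin synthase, had 1 count in DKO and 142 in MycKO, a ratio of 113 (95% counting interval 20 to 4500), and BC018473 had 380 and 2, a ratio of 238 (65.5 to 1970).

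In all, 1592 of 13397 genes changed in DKO against MycKO, 584 up and 1008 down. Mlx fell by 0.50 ± 0.10 on the log2 scale (adjusted p = 0.0052), Mycl by 1.75 ± 0.33 (adjusted p = 0.0035), and Myc did not pass the test (−0.34 ± 0.47, adjusted p = 0.66, lower in 4 of 5). Without single libraries the count was 903 (MycKO 2), 1013 (MycKO 5), 967 (DKO 4) and 892 (DKO 5), with length and GC offsets it was 939, and with the shared term it was 78, 43 up and 35 down, of which 42 were among the 1592. The authors' deposited table lists 1259.

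DKO against MlxKO asks what loss of Myc adds where Mlx is already absent, and 5 of 13397 genes changed. Myc fell 7.61-fold (log2 −2.93 ± 0.47, adjusted p = 0.017) and Gpatch4 fell from 12.3 CPM ± 1.62 to 4.91 ± 0.404 (−1.32 ± 0.17, adjusted p = 0.0016). Rpl36a fell by 0.81 ± 0.15 (adjusted p = 0.049) and the noncoding gene AI506816 fell by 2.05 ± 0.37 (adjusted p = 0.049). Lratd2 rose from 6.48 CPM ± 1.46 to 28.1 ± 5.50 (2.11 ± 0.30, adjusted p = 0.0049). Mlx did not pass the test (−0.16 ± 0.11, adjusted p = 0.95, lower in 5 of 5). Of 79 ribosomal protein genes 69 were lower adjusted over the list alone (median −0.50, camera adjusted p = 2e-84, adjusted p = 0.0736 with an estimated correlation). Over all genes edgeR called 1 of them, 15 in a fit of these groups alone, 7 without WT 2, WT 5 and MycKO 5 and 12 with length and GC offsets, and DESeq2 called 21. The 1 call, Rpl36a, was lost with RLE factors, in males only, with the shared term, without genes near the targeted loci and without each single MlxKO or DKO library except DKO 3 (adjusted p = 0.052 to 0.2). With those offsets the list also passed the estimated correlation (adjusted p = 0.014). Lower adjusted over the list alone were also 5 of 63 ribosome biogenesis genes (median −0.22, camera adjusted p = 1.91e-16, adjusted p = 0.144 with an estimated correlation). Nucleotide and one-carbon synthesis genes, 32 in number, had a median of −0.26 with 2 lower adjusted over the list alone, and passed both camera (adjusted p = 1.84e-05) and the estimated correlation (adjusted p = 0.0475). The count of changed genes was 46 with DESeq2, 22 in a fit of these groups alone, 20 with length and GC offsets, 15 without WT 2, WT 5 and MycKO 5, 3 with RLE factors, 1 without genes near the targeted loci and 2 in males only. It was 1 without MlxKO 2, 3 without DKO 2 and 2 without each of MlxKO 1, DKO 1, DKO 4 and DKO 5. The authors' deposited table lists 14.

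The interaction asks whether the DKO effect departs from the sum of the MycKO and MlxKO effects on the log scale. With edgeR 0 of 13397 genes passed, 469 had an unadjusted p under 0.05 where 670 are due to chance, and the smallest adjusted p was 0.0991. DESeq2 called 4 genes and limma-voom 0, and edgeR called 1 without each of WT 5, MycKO 1, MycKO 5, DKO 4 and MlxKO 3. Myc departed by 0.01 ± 0.66 and Mlx by −0.04 ± 0.14. Ribosomal protein genes departed by a median of −0.17 (camera adjusted p = 2.55e-07, adjusted p = 0.903 with an estimated correlation). ER stress genes departed by 0.25 (camera adjusted p = 0.000269, adjusted p = 0.903 with an estimated correlation) and T and NK cell markers by −0.91 (camera adjusted p = 0.000269, adjusted p = 0.824 with an estimated correlation). On simulated data this test recovered 25.4% of 2-fold departures, so departures of that size could be missed.

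**Figure D4:**
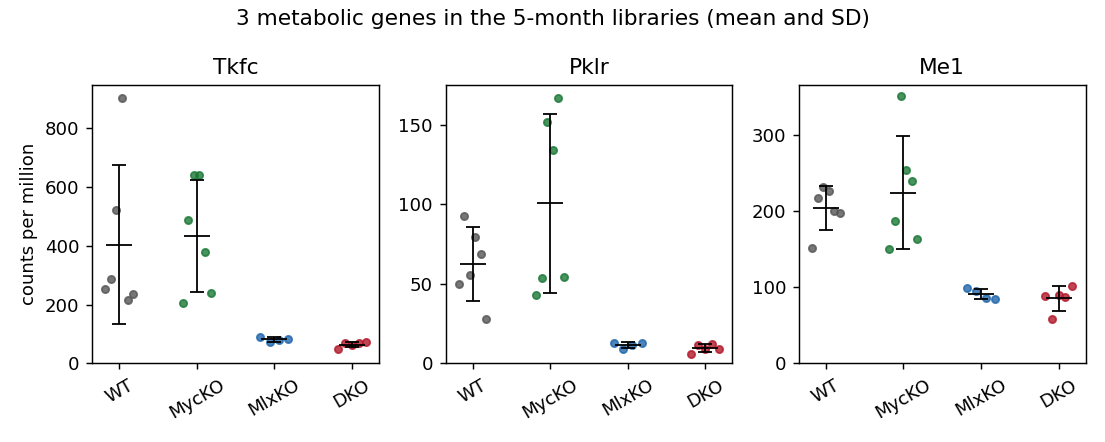
CPM of Tkfc, Pklr and Me1 in each 5-month library of WT, MycKO, MlxKO and DKO, with bars at the mean and SD. Pklr has a mean of 62.5 in WT, 11.5 in MlxKO and 9.70 in DKO.

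Adenomas against old WT liver asks how tumours that arose in Mlx-deleted livers differ from liver of like age. The data hold no old Mlx-deleted liver without a tumour. Effects of the tumour therefore cannot be told apart from those of Mlx loss or of the Cre driver. Every adenoma library also had a higher total count and a larger share of even low counts than every old WT library. A difference in processing between the groups thus cannot be told apart from a difference in the tissue. Fabp1, the liver fatty acid binding protein, fell 12.4-fold, from 2450 CPM ± 1150 to 196 ± 51.3 (log2 −3.63 ± 0.41, adjusted p = 0.00074). Of 42 fatty acid oxidation and PPAR alpha targets 30 fell, including the carnitine carrier Slc25a20 (−1.60 ± 0.19), Etfdh (−1.49 ± 0.21) and Decr1 (−1.70 ± 0.25). Adjusted over the list alone 34 were lower (median −1.11, camera adjusted p = 6.31e-20, adjusted p = 0.229 with an estimated correlation). Of 30 ChREBP targets 12 fell, including Pklr, from 327 CPM ± 140 to 28.9 ± 8.71 (−3.13 ± 0.30), Khk (−2.14 ± 0.21), Slc2a2 (−2.43 ± 0.29) and Mid1ip1 (−1.73 ± 0.23), with a camera adjusted p of 3.09e-10 (adjusted p = 0.229 with an estimated correlation). Among the tumour markers Lcn2 (lipocalin 2) was 28.8-fold higher in the fit with its sex term, with means of 11.2 CPM ± 6.16 in WT and 507 ± 377 in adenomas.

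Many genes of the respiratory chain also fell in the adenomas. Complex I had 24 falls of 36, including Ndufb3 (log2 −1.59 ± 0.20), Ndufa3 (−1.53 ± 0.23), Ndufb8 (−1.17 ± 0.18) and Ndufs6 (−1.51 ± 0.23). Complexes II to V had 27 falls of 39, including Uqcrb (−1.53 ± 0.19), Sdha (−1.33 ± 0.18), Uqcr11 (−1.67 ± 0.29) and Sdhd (−0.89 ± 0.17). Camera adjusted p-values were 1.28e-16 and 1.41e-14, and with an estimated correlation adjusted p = 0.229 and 0.238. Mitochondrial ribosomal proteins had 24 falls of 78, including Mrps5 (−1.39 ± 0.21), Mrpl50 (−0.99 ± 0.15), Mrps31 (−1.24 ± 0.19) and Mrpl2 (−1.0 ± 0.18), with a camera adjusted p of 2.28e-10 (adjusted p = 0.259 with an estimated correlation). The TCA cycle had 11 falls of 17, including citrate synthase Cs (−1.28 ± 0.15), Suclg2 (−1.16 ± 0.16) and Pdha1 (−1.05 ± 0.17), with a camera adjusted p of 9.56e-10 (adjusted p = 0.229 with an estimated correlation). Cytoplasmic ribosomal proteins had 2 rises and 1 fall of 79, with a median of −0.03 (camera adjusted p = 0.383).

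Of 35 liver tumour markers 18 rose in the adenomas, including S100a11 (log2 2.34 ± 0.28), Golm1 (2.62 ± 0.34) and H19, an imprinted noncoding RNA (median of the list 2.06, camera adjusted p = 2.53e-13, adjusted p = 0.216 with an estimated correlation). H19 rose from 0.401 CPM ± 0.338 to 2760 ± 3350, with single adenomas between 77.3 and 6680. Of 21 immediate early genes 17 rose, including Fos (3.13 ± 0.37), Atf3 (3.21 ± 0.45), Btg2 (2.34 ± 0.33) and Klf6 (1.89 ± 0.29), with a camera adjusted p of 1.74e-11 (adjusted p = 0.216 with an estimated correlation). Neutrophil markers had 6 rises of 7 and T and NK cell markers 4 of 13 (camera adjusted p = 0.000975 and 0.000775, and with an estimated correlation adjusted p = 0.412 and 0.507). In these 2 lists limma-voom called 0, DESeq2 called 6 and 8, and 6 and 10 were higher at an unadjusted p under 0.05 in edgeR. Extracellular matrix genes had 12 rises of 33 (camera adjusted p = 1.92e-07, adjusted p = 0.412 with an estimated correlation). Markers of hepatic stellate cells and fibroblasts had 5 rises of 18, of Kupffer cells and macrophages 5 of 18 and of cholangiocytes 5 of 11 (camera adjusted p = 0.0431, 0.00543 and 0.00121, and with an estimated correlation adjusted p = 0.757, 0.66 and 0.335). Limma-voom called 9 of the tumour markers, 7 of the matrix genes and 3 in each of these marker lists. The largest rises beyond H19 were those of Igf2, the growth factor of the same imprinted locus, from 0.739 CPM ± 0.225 to 1970 ± 2820 with adenomas between 2.09 and 6150, and Tff3, a trefoil peptide (9.69 ± 1.51), neither of which passed with limma-voom (adjusted p = 0.2 and 0.14). Sprr1a had 0 counts in WT and 2719 in the adenomas, at least 331-fold higher against a floor of 3 counts over the group. Gldn (3 and 10717 counts) and Spink1 (3 and 3895) had ratios of 1300 (446 to 6320) and 474 (162 to 2300) after scaling. The largest falls were all in major urinary protein genes, Mup12 (−8.50 ± 1.31), Mup15 (−8.28 ± 1.64), Mup19 (−8.28 ± 1.25), Mup1 (−8.14 ± 0.94), Mup13 (−8.00 ± 0.89) and Mup2 (−7.33 ± 0.83). These are near-identical copies, so single values are uncertain.

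**Figure D5:**
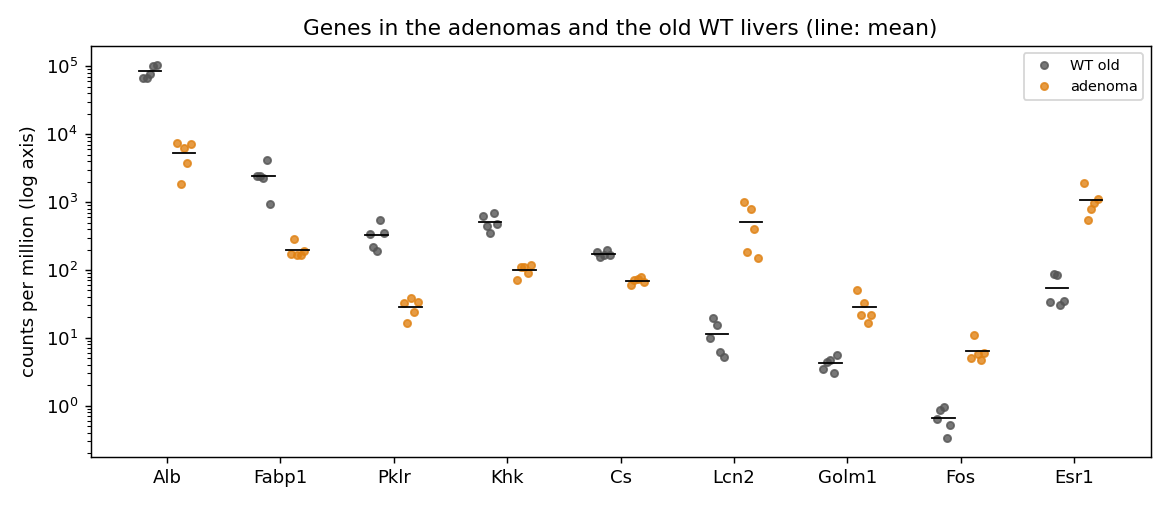
CPM on a log axis of 9 genes in each of 5 adenomas and 5 old WT livers, with lines at the means. Fabp1 has means of 196 in adenomas and 2450 in WT, Pklr 28.9 and 327, and Lcn2 507 and 11.2, with no overlap between the groups for these 3.

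In all, 2290 of 13954 genes changed in adenomas against old WT, 1219 up and 1071 down, of which 1450 by at least 2-fold. Mlx was lower in 5 of 5 without passing (log2 −0.55 ± 0.17, adjusted p = 0.052, and 0.036 and 0.04 without adenoma 1 and adenoma 4). Its log2 fold change was −0.33 without adenoma 5. It passed with DESeq2, RLE factors, the stricter filter, no sex term and halved counts. Myc was higher in 5 of 5 without passing (1.52 ± 0.56, adjusted p = 0.087). Of the Myc antagonists, Mxd1 rose (0.91 ± 0.23, adjusted p = 0.022) and Mxd4 fell (−0.68 ± 0.21, adjusted p = 0.047). Adenoma 5 was the only adenoma labelled male, and its Xist and Y-linked counts go against that label. Except where stated, the adenoma values of genes and lists come from the fit that kept the label, so they rest on a doubtful sex term. With adenoma 5 taken as female 1005 genes passed, 449 up and 556 down, of which 943 were among the 2290. The count was 165 in females only, 692 with the 17-month adenomas alone, 3486 with no sex term, 3525 with DESeq2, and 728, 704 and 806 without adenoma 5, WT 2 and WT 3. Limma-voom called 1713, 649 up and 1064 down. The authors' deposited table lists 3343.

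Effects were then set side by side. Between MlxKO at 5 months and the adenomas, over 12298 genes tested in both sets, 22 genes fell in both where 10.5 are due to chance (Fisher's exact test, p = 0.00093), 8 rose in both against 6.34 (p = 0.53) and 28 moved in opposite directions against 17.0. Fold changes correlated across genes at Pearson's r = 0.04 and Spearman's rho = 0.07. The MlxKO effect and DKO against MycKO share no library but share the sex term, and each sets males that read alike for Kpna2 and Gm10184 against libraries that mostly or all read the other way. In both, 59 genes rose and 113 fell, against 3.71 and 10.7 due to chance, and 0 moved in opposite directions against 12.6. Their r was 0.68 (rho = 0.70) with a covariance of 0.22, against 0.10 and 0.01 in simulated tables with no effect. With the shared term 43 rose and 33 fell in both, and r was 0.90 with a covariance of 0.84, against 0.79 and 0.36 in simulated tables fitted with that term. The MycKO effect and DKO against MlxKO shared 2 falls (Myc and Gpatch4), at r = 0.13 (rho = 0.20), against −0.01 in simulated tables with no effect. MlxKO and DKO effects share the WT libraries, and 78 genes rose and 131 fell in both where independent lists give 6.44 and 15.5, while 1 moved in opposite directions against 20. Their r was 0.81 with a covariance of 0.26, against 0.48 and 0.05 in simulated tables with no effect and 0.52 and 0.20 with WT divided between them. MycKO and MlxKO effects shared 3 falls and 2 genes moved in opposite directions, where independent lists give 0.0848 and 0.0932, and they had r = 0.23 and covariance 0.04, against 0.43 and 0.04 simulated and −0.07 and −0.02 with WT divided. MycKO and DKO effects shared 2 rises and 6 falls and 3 genes moved in opposite directions, where independent lists give 0.303, 0.872 and 1.04, and they had r = 0.29 and covariance 0.06, against 0.45 and 0.04 simulated and −0.01 and −0.01 with WT divided. Genes are not independent replicates, so these correlations carry no p. These 6 pairs were the only ones compared.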

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

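The tests of additive effects, of the hepatocyte share, of strain DNA, of the WT background, of copies of BC018473 and of the sex of the mice were chosen only after the result was seen, as were the removal of WT 2, WT 5 and MycKO 5, the length and GC offsets, the halved adenoma counts and the term shared by the WT females, MlxKO and DKO.

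Single libraries stood far from the rest of their group in 36 of 452 groups tested (7.96%), where chance gives about 1 in 20. In 5 of the 36 all other libraries were at 0, so that the gap was the whole range by construction, and without these 31 of 447 groups remain (6.94%). Among WT libraries at 5 months, WT 2 was high for Psmb9 (10.6 CPM, others 5.28 to 6.82) and Bst2 (196, others 68.8 to 110), and WT 3 for Vldlr (5.05, others 0.611 to 2.21) and Acot5 (1.24, others up to 0.166). WT 4 was high for Hspa5 (845, others 296 to 403) and Derl3 (1.83, others 0.105 to 0.576). In MycKO the high libraries were MycKO 1 for BC018473 (0.0964 CPM), MycKO 2 for Cpne5 (10.5) and Obp2a (16.6), MycKO 3 for Acot5 (5.47) and Aqp3 (1.95), and MycKO 5 for Serpina12 (38.6), Hsd3b5 (181, others up to 6.12) and Rtp4 (16.3). In DKO they were DKO 1 for Cpne5 (28.8 CPM), DKO 2 for Mrpl38 (37.4), DKO 3 for Rtp4 (5.84) and for the total count (28476797, others up to 20337377), and DKO 4 for Ptgds (0.049 CPM, others at 0). In MlxKO they were MlxKO 1 for Cspg5 (1.16 CPM) and Obp2a (1.49), MlxKO 2 for BC018473 (13.7, others 2.14 to 3.56) and MlxKO 3 for Zfp708 (0.38). Among the adenomas, adenoma 1 was high for S100a11 (49.5 CPM), Mup12 (0.594), Mup15 (23.6) and Mup19 (69.8) and low for Uqcrb (27.5, others 41.9 to 45.4). Adenoma 2 was high for Fabp1 (286) and Fos (11), and adenoma 5, the library labelled male, was high for Mup13 (0.0971). In old WT, WT 1 was high for Myc (10.6 CPM, others 1.98 to 3.66) and Mup2 (627), WT 4 for Gldn (0.201) and Tff3 (1.27), and WT 5 was low for Mrps5 (19.8, others 38.0 to 45.4).

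The effect of Myc loss differed between males and females for 4 of 13397 genes in edgeR's test of the difference, with 2 females per group. In that test 1754 genes had an unadjusted p under 0.05 where 670 are due to chance, so the difference may reach beyond these 4. The main fit gives all groups the same sex effect and leaves such a difference out. The 4 genes were Kpna2 (adjusted p = 1.38e-05), Gm10184 (adjusted p = 0.00533), Slc36a1 (adjusted p = 0.0212) and Trrap (adjusted p = 0.0217). Slc36a1 had means of 18.9 CPM in WT males and 9.85 in WT females, and 14.9 and 23.9 in MycKO. Trrap had means of 33.6 and 18.0 CPM in WT, and 23.5 and 33.3 in MycKO. The 2 WT females belong to the 11 libraries that Kpna2 and Gm10184 part from the other 10, and in this design a term for those 11 is the same as a Myc effect that differs by sex, so none of the 4 genes is shown to differ by sex.

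Kpna2, Gm10184, BC018473 and Cyb561 were the 4 of 13797 genes that parted 11 libraries (the WT females, MlxKO and DKO) from the other 10, and 3 of them lie on chromosome 11. Mlx lies on that chromosome too (101087277 to 101092207). Cyb561 (105933702 to 105953336) and Kpna2 lie within 10 Mb of Mlx and BC018473 (116752167 to 116759373) beyond. The WT females share the pattern although Mlx is not knocked out in them. Sex was argued against, since the lowest male MlxKO or DKO library had at least 212-fold more Gm10184 than the male WT libraries, all at 0, against a floor of 3 counts per library (a first test, between the sexes of MycKO, gave 2.02-fold). For Kpna2 and Gm10184 a candidate explanation is that reads of near-identical copies were counted differently in 2 sets of libraries, as 95.8% of the 31-base words of Gm10184 occur in Kpna2 and their sum was 43.4 CPM ± 6.38 (n = 11) in one set and 47.9 ± 8.63 (n = 10) in the other, but for BC018473 only 0.3% of words occur in its closest gene, which argues against it there. WT livers of more than one genetic background stay open, untested, because the gap of at least 22.5-fold between WT 3 and WT 4 and the other WT libraries for Gm10184 and BC018473 restates the pattern. DNA of another strain around the targeted loci also stays open with so few genes near them, as 10 of 231 genes called in MycKO or MlxKO lay within 10 Mb where 6.88 are due to chance (one-sided Fisher's exact test, p = 0.15, smaller in an earlier version that counted the targeted genes), while in MycKO alone 3 of 10 did against 0.298 (p = 0.0027, the smallest of 5 single comparisons, the others at 0.11 to 0.36), which goes with it.

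The lower ribosomal protein genes in DKO, at a median log2 fold change of −0.96 as reported, kept −0.73 with length and GC offsets. Without WT 2, WT 5 and MycKO 5 the median was −0.87. These values argue against each of these as the whole cause. With the shared term the median was −1.31. That term is the same as a Myc effect that differs by sex and is fitted without MlxKO or DKO. It therefore cannot decide on a cause shared by the 11 libraries. The median in DKO lay −0.17 from the sum of the medians in MycKO and MlxKO as reported and −0.31 with the shared term, so separate additive effects of Myc loss and Mlx loss cannot be told apart from a departure. The median of the interaction, −0.17 as reported, was −0.31 with the shared term and in males only, −0.07 without WT 6, −0.10 without MlxKO 3 and −0.26 without WT 2 or WT 4. In males only the median was −0.88, so the sex of the livers does not account for the fall.

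In the adenomas Alb fell 14.0-fold (84100 CPM ± 18500 to 5350 ± 2450, adjusted p = 0.0009, n = 5 each) and Esr1 rose 17.9-fold (53.9 ± 28.5 to 1060 ± 521, adjusted p = 0.00039), genes chosen after their values were seen. The other 36 secreted liver proteins had a median of −0.27, which argues against a lower share of hepatocytes as the whole cause of the fall of Alb. A smaller loss of hepatocytes was not tested, and by camera markers of several other cell types were higher in the adenomas. The counting of both reads of a pair was not tested by halved counts, which the scaling absorbs (a move of 0.01 at most). Whether reads of the Cre-ERT2 transgene, which holds part of the estrogen receptor, were counted as Esr1 cannot be told apart from a change of Esr1 itself, because the 5-month knockouts, with the transgene under another driver, had a log2 fold change of 0.63 at most (smallest adjusted p = 0.13). Alb drives Cre-ERT2 in the adenoma mice per the labels, and a change of both genes in the tumours themselves stays open, untested.

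Of 100 splits of the libraries into groups of the same sizes, the real one included, 1 gave as many genes as DKO against WT (2475, highest other 1562). It was also 1 for DKO against MycKO (1592, highest other 1416), DKO against MlxKO (5, highest other 1) and adenoma against WT (2290, highest other 8). The split with 1562 set WT 1, WT 2, WT 4, WT 5 and WT 6 against WT 3 and all DKO. That with 1416 set MycKO 1, MycKO 2, MycKO 3, MycKO 5 and MycKO 6 against MycKO 4 and all DKO. Both nearly reverse the real groups, so these 2 counts do not show what unrelated groupings give. For MlxKO against WT 2 splits gave as many (227), and the other of them gave more (393). This argues against chance for these tests without excluding it. The splits cannot tell genotype from anything else that follows the labels. For MycKO against WT 12 splits gave at least its 12 genes, with up to 1438 in another split, which points to a structure of the samples, and chance cannot be excluded. For the interaction the splits decide nothing, since all 100 gave at least its 0 genes by edgeR (469 unadjusted, DESeq2 4, limma-voom 0). The highest other split gave 1371 and the next 35.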

How the results depend on the processing

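The removal of WT 2, WT 5 and MycKO 5, length and GC offsets, halved adenoma counts, adenoma 5 as female and the term shared by the WT females, MlxKO and DKO were chosen only after the data were seen. Where a cause is not given below, the cause was not tested. No paired analysis was possible because replicate numbers only name samples here and the labels carry no pairing.

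Named genes kept direction and call in 2019 of 2314 values under other settings (276 weaker, 8 stronger, 11 reversed) and in 1951 of 2152 with 1 library left out (197 weaker, 4 stronger, 0 reversed). Gene lists did so in 1322 of 1682 (343 weaker, 17 reversed) and 1465 of 1605 (140 weaker). With an estimated correlation the lists past camera numbered 0 for MycKO, 1 each for MlxKO, DKO, DKO against MycKO and DKO against MlxKO, 0 for the interaction and 0 for adenoma, against 14, 22, 27, 21, 21, 10 and 29. With fry they numbered 3, 10, 26, 17, 3, 0 and 16 in the same order.

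DESeq2 called 71 genes for MycKO, 846 for MlxKO, 46 for DKO against MlxKO, 4 for the interaction and 3525 for adenoma, gave 1.77 for Gm10184 in MycKO, and put Mlx in adenoma past the threshold (−0.56, adjusted p = 0.033, and 0.013 to 0.45 over its settings). So did RLE factors (−0.56), the stricter filter (−0.53), no sex term (−0.61) and halved counts (−0.55), while RLE factors left 3 genes for DKO against MlxKO and no filter ended the call of Mlx in MlxKO (−0.44, adjusted p = 0.082). With no sex term 7 genes passed for MycKO, 122 for MlxKO and 3486 for adenoma, and the test of male-biased genes turned (medians −0.35 in MlxKO, 0.04 in DKO and 0.00 in DKO against MycKO). Limma-voom called 19 for MycKO. At 2-fold or more 115 remained for MlxKO, 595 for DKO, 436 for DKO against MycKO and 1450 for adenoma, by construction. Without genes near the targeted loci 1 passed for MycKO and 1 for DKO against MlxKO.

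Males alone, with fewer libraries, gave 2 genes for MycKO, 96 for MlxKO, 1520 for DKO and 2 for DKO against MlxKO. Males also gave Myc in MycKO at −2.84 (adjusted p = 0.16), Mlx in MlxKO at −0.41 (adjusted p = 0.1), Gm10184 in MycKO at 4.27, and turned tests of mitochondrial ribosomal proteins (0.01) and complexes II to V (0.04) in MycKO and of secreted proteins in the interaction (0.00). Females alone gave 165 for adenoma, and the 17-month adenomas alone 692. With only the groups compared 1 passed for MycKO (Myc −2.94, adjusted p = 0.071), 38 for MlxKO (Mlx −0.41, adjusted p = 0.21), 1220 for DKO and 22 for DKO against MlxKO.

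Without WT 2, WT 5 and MycKO 5 there were 22 lists for MycKO, 82 genes for MlxKO (Mlx −0.47, adjusted p = 0.082), 1298 for DKO, 15 for DKO against MlxKO and 1 for the interaction. Also without these libraries, the tests of NRF2 targets in MlxKO (0.05) and cytochrome P450 genes in DKO (0.02) turned. Length and GC offsets gave Mlx in MlxKO −0.28 (adjusted p = 0.17), 1514 genes for DKO, 939 for DKO against MycKO and 20 for DKO against MlxKO. The shared term gave 2 genes for MycKO (Myc −2.84, adjusted p = 0.073), 664 for MlxKO, 1520 for DKO and 78 for DKO against MycKO. It turned Gm10184 (4.31 in MycKO, −4.61 in MlxKO, −4.40 in DKO), BC018473 (−2.43 in MlxKO, −3.08 in DKO, −3.03 in DKO against MycKO) and Kpna2 (6.02, 5.73 and 5.70). The shared term turned camera's direction, medians in brackets, for mitochondrial ribosomal proteins (0.01) and complexes II to V (0.04) in MycKO. It did so for fatty acid oxidation (−0.06) and ER stress (0.19, still positive) in MlxKO, and for secreted proteins in the interaction (0.00). In DKO against MycKO it did so for genes of the mitochondrial genome (−0.15), fatty acid oxidation (−0.10), beta-catenin targets (−0.42) and cholangiocyte markers (−0.07). Adenoma 5 as female left 1005 genes. The correlation of MlxKO with adenoma was −0.02 for males by females, that of MlxKO with DKO against MycKO was 0.90 with the shared term, and with WT divided the shared-control correlations were −0.07, −0.01 and 0.52.

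With 1 library left out, counts ran from 2 to 25 for MycKO (lists 12 to 21, Myc −3.14 to −2.68), 45 to 1055 for MlxKO (lists 20 to 25, Mlx −0.50 to −0.38) and 1218 to 3195 for DKO (lists 24 to 28, Myc −3.60 to −2.96, Mlx −0.65 to −0.57). The counts ran from 892 to 1772 for DKO against MycKO (lists 18 to 22), 1 to 6 for DKO against MlxKO (lists 18 to 23), 0 to 1 for the interaction (lists 8 to 17) and 704 to 2906 for adenoma (lists 24 to 32, Mlx −0.65 to −0.33). In simulated data 2-fold changes were recovered at 65.7% in MycKO and 11.9% in adenoma, so changes of that size could be missed in the adenomas at this depth and spread.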

Other observations

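The genes named here from outside the fixed rule were chosen after their values were seen, and the lists were fixed before.

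The adenomas also differed from old WT in groups not described above. Of 26 acute phase genes 8 rose, including Saa1 (log2 2.42 ± 0.52), with a camera adjusted p of 0.00137 (adjusted p = 0.412 with an estimated correlation), and DESeq2 called 13. Of 21 imprinted genes 9 rose, including the noncoding RNAs Meg3 (5.45 ± 1.08) and Rian (5.32 ± 0.98), which are also on the list of liver tumour markers, with a camera adjusted p of 0.000754 (adjusted p = 0.229 with an estimated correlation), and limma-voom called 3. Of 51 cell cycle genes 8 rose and 1 fell, with Mki67 among the rises (2.28 ± 0.55), with a camera adjusted p of 3.71e-05 (adjusted p = 0.66 with an estimated correlation). Limma-voom called 0 rises and 1 fall among them, DESeq2 called 26 rises, and 27 were higher at an unadjusted p under 0.05 in edgeR. Of 28 beta-catenin targets and perivenous genes 6 fell (12 with DESeq2 and 9 with limma-voom), with a camera adjusted p of 4.29e-07 (adjusted p = 0.412 with an estimated correlation), and Oat, also on the list of the urea cycle and amino acid catabolism, fell (−2.87 ± 0.79, adjusted p = 0.0326). Of 32 proteasome genes 12 fell (camera adjusted p = 7.74e-07, adjusted p = 0.238 with an estimated correlation). The collagens Col1a1 (2.58 ± 0.43) and Col3a1 (1.86 ± 0.40) and the neutrophil genes S100a8 (3.10 ± 0.75), S100a9 (3.22 ± 0.60) and Ngp (4.38 ± 1.34) were also higher, as was hemopexin Hpx (1.36 ± 0.33), a secreted liver protein. Nucleotide and one-carbon synthesis genes had 4 rises and 5 falls of 33 (camera adjusted p = 0.683).

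At 5 months, Kupffer cell genes chosen after their values were seen were lower in DKO against WT, with Marco at −2.80 ± 0.59 and Adgre1 at −1.0 ± 0.31 on the log2 scale. So were the hemoglobin genes Hba-a1 (−1.56 ± 0.49) and Hbb-bs (−1.44 ± 0.48). Gt(ROSA)26Sor was lower in all 3 knockouts at 5 months, by log2 −1.67 ± 0.27 in MycKO, −1.81 ± 0.33 in MlxKO and −0.98 ± 0.29 in DKO, and higher in the adenomas by 1.45 ± 0.28. Mug2 was lower in all 3 knockouts (−3.10, −4.65 and −4.57) and higher in the adenomas (1.67 ± 0.29). The list of nucleotide and one-carbon synthesis had 7 falls of 32 in DKO against WT (camera adjusted p = 0.00641, adjusted p = 0.247 with an estimated correlation).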
